A study of Mus musculus with 6 samples.

How the data were processed

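Gene expression was measured by RNA sequencing in 6 libraries of bone marrow cells selected with CD8 microbeads, 3 from mice with immune bone marrow failure given ruxolitinib and 3 from control mice with the same disease. Each library was a pool of 2 to 3 mice, per the labels. Total RNA was made into libraries with the NEBNext Ultra II kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.5 as aligner and the mm10 mouse genome. The counting program, its strand setting, its treatment of reads that match several genes and the annotation release are not given in the sources used here. How long the mice were treated, at what dose and when marrow was taken are not given there either.

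The deposited table holds raw read counts per gene, not normalised, as whole numbers with a different total in each library. It lists 54532 genes with Ensembl identifiers, symbols, positions, biotypes and a gene length in bases, and 31500 of them have no count in any library. The length is as deposited, and how it was measured is not given in the sources used here. Of the identifiers, 54409 are in GENCODE release M21 (GRCm38, the assembly of mm10) and 98.3% of those have the same coordinates there. Groups were taken from the sample labels, and table columns were matched to samples by the names in the titles. The pools are numbered 1 to 3 for ruxolitinib and 4 to 6 for controls.

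Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr on the groups, TMM factors, glmQLFit with robust estimation, glmQLFTest, group as the only term), with Benjamini-Hochberg adjusted p under 0.05 as threshold. The filter kept 13480 genes. The SE of a log2 fold change was its size divided by the square root of the F statistic. Where a gene had 0 counts in all libraries of a group, the fold was computed against a floor of 3 counts over the group and is a lower bound. Intervals and floors cover counting error only, since reads are not independent molecules. The libraries held 13829808 to 17708196 counts, so a gene near 1 CPM rests on few reads and has a large counting error. Library shares were compared with exact two-sided permutation tests, which cannot give p under 0.1 for 3 against 3.

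Before the data were examined, 27 gene lists were fixed, covering interferon response, cytotoxicity and other T cell programmes, cytokine signalling, metabolism, stress and markers of the other cells of the marrow. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 26 lists tested, and again with a correlation estimated per list. Members past the threshold were counted over all genes tested and again adjusted over the list alone. The rule for naming genes was fixed at the same time. It took the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group, non-overlapping groups and an established symbol that is no immunoglobulin or T cell receptor segment. It added up to 4 called members with the smallest p in each list of a T cell or signalling programme, or 1 uncalled member where none was called, the 2 most abundant members of each quality or cell type list, and Jak1, Jak2, Jak3, Tyk2, Cd8a, Cd8b1, Ifng and Fas. The results of some of the genes this rule or a list takes are not reported here.

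Alternatives fixed before the data were examined were RLE and upper-quartile factors, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, protein-coding genes alone, a 2-fold minimum, leaving out each pool, estimated correlations, the fry test and, for library shares, the counts in filtered genes alone as denominator. After the CD8 identity genes were seen to fall as a list, 4 alternatives were added: scaling each library to the geometric mean of the 17 identity genes, removing haemoglobin genes before normalisation, total-count scaling with and without haemoglobin genes, and offsets per library for gene length and GC content (8 by 5 bins) together with the identity scaling. Scaling to the identity genes reports every gene relative to T cell content as those genes measure it. It assumes that the identity genes do not themselves respond to the drug, which cannot be checked in these data. The SE was larger under this scaling for 13292 genes and smaller for 188, with a median of 0.603 against 0.297. An eosinophil and basophil list and a haem and iron list were also added after the data were seen.

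The scripts were tested on simulated counts for the ruxolitinib against control comparison, 3 simulated libraries each, with 13246 genes in the step. The edgeR test called 20 of 98 genes changed by 2-fold and 80 of 98 changed by 4-fold, and 15 unchanged genes, 11.5% of its calls. DESeq2 called 124 and limma-voom 92 of the changed genes. With 1 list lowered, camera called 1 further list and fry 0. A further simulation lowered the identity and cytotoxic genes by an equal amount and left all other genes unchanged. There CD8 identity scaling called 2 cytotoxic genes, both higher, and left their median at 0.22. It tests the scaling step only, since it does not model a changed cell mix or a spread among identity genes. No 2 libraries agreed within sampling noise: the smallest chi-square per degree of freedom over genes was 19.6, between control pools 4 and 5.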

Results

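Messenger RNA was measured in cells selected with CD8 magnetic beads from the bone marrow of female CByB6F1 mice, an F1 hybrid strain, aged 2 to 5 months. The mice had immune bone marrow failure, a model in which T cells attack the blood-forming cells of the marrow. In 3 libraries the mice had received ruxolitinib, an inhibitor of the kinases JAK1 and JAK2, which carry the signals of interferon and many other cytokine receptors, and in 3 control libraries they had not. Each library came from a pool of 2 to 3 mice of the same group, so the 6 libraries are separate biological samples. The ruxolitinib libraries held 14139605, 13829808 and 14002397 counted reads (pools 1 to 3) and the control libraries 17708196, 15740514 and 16642610 (pools 4 to 6). The design gives a single comparison, ruxolitinib against control, which asks how the drug alters gene expression in these marrow CD8 cells. Expression levels are given as CPM, the count of a gene divided by its library's total and edgeR's TMM factor, as mean ± SD over 3 pools. Fold changes are ruxolitinib over control on the log2 scale ± SE, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named.

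Among the 8 largest falls in the ruxolitinib libraries were Ly6a, Gzma, Ifit1 and Rtp4. Ly6a, which encodes the interferon-inducible surface protein Sca-1, fell from 684 ± 65.5 CPM to 11.1 ± 12.6 CPM (log2 fold change -5.93 ± 0.80, adjusted p = 0.000299, and -7.45 without ruxolitinib pool 3). Gzma, which encodes the cytotoxic protease granzyme A, fell from 113 ± 45.3 CPM to 2.32 ± 1.19 CPM (-5.58 ± 0.45, adjusted p = 2.30e-05). The interferon-stimulated antiviral gene Ifit1 fell from 43.7 ± 17.7 CPM to 1.03 ± 0.193 CPM (-5.39 ± 0.37, adjusted p = 1.66e-05). Rtp4, another interferon-stimulated gene, fell from 50.2 ± 1.28 CPM to 1.89 ± 0.860 CPM (-4.71 ± 0.33). The others were in Mt3, a metallothionein gene (-5.22 ± 0.60, and -5.98 without ruxolitinib pool 3), Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf (-4.75 ± 0.55, and -5.61 without ruxolitinib pool 3), and Hopxos (-5.05 ± 0.74, and -4.32 without control pool 6), an antisense gene whose reads cannot be told from those of Hopx because the strand setting of the counting is not given in the sources used here. Retnla, which encodes a secreted resistin-like protein, had 0 counts in all 3 ruxolitinib pools and 8.93 ± 7.29 CPM in controls, at least 125-fold lower against a floor of 3 counts over the group (at least 66.5-fold without control pool 6). Gzma lies on chromosome 13 at 113093825 to 113100981, Ifit1 on chromosome 19 at 34640871 to 34650009 and Ly6a on chromosome 15 at 74994877 to 74998031 (mm10, positions as deposited). Near-identical relatives of Ifit1 and Ly6a lie in the same gene families, so part of their counts could be shared with those copies.

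All 8 of the largest rises by edgeR's fold change were in genes with 0 counts in the 3 control pools, and their folds are lower bounds against the same floor. With 0 counts in a group edgeR's fold is not a measured size, so these bounds do not show that the 8 genes rose most. Slc6a9, a glycine transporter gene used by developing red cells, reached 55.9 ± 22.3 CPM, at least 899.7-fold higher. Spib, a transcription factor gene of B cells and plasmacytoid dendritic cells, reached 41.9 ± 6.51 CPM (at least 696-fold), and Ms4a1, which encodes the B cell antigen CD20, reached 27.2 ± 5.38 CPM (at least 449-fold). Ly6d, a marker of early B cells and plasmacytoid dendritic cells, reached 20.9 ± 2.36 CPM (at least 343-fold). The others were the carnitine and ergothioneine transporter gene Slc22a4 (at least 401-fold), the angiotensin-converting enzyme gene Ace (at least 248-fold), the calcium channel gene Cacna1g (at least 228-fold) and the pseudogene Cyp4b1-ps2 (at least 219-fold), whose reads could belong to its parent family.

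Genes that define CD8 T cells were lower in the ruxolitinib libraries although the cells of both groups had been selected with CD8 beads. Cd8a, which encodes the CD8 alpha chain, fell from 944 ± 118 CPM to 286 ± 173 CPM (log2 fold change -1.72 ± 0.39, adjusted p = 0.00441), and Cd8b1, the beta chain gene, fell by a similar size (-1.73 ± 0.39, adjusted p = 0.00436). The T cell receptor constant gene Trbc2 fell from 2169 ± 533 CPM to 370.2 ± 184 CPM (-2.55 ± 0.40) and the T cell surface gene Thy1 from 1423 ± 126 CPM to 366 ± 216 CPM (-1.96 ± 0.39). Of the 17 CD8 T cell identity genes, 16 fell. All 17 passed when p was adjusted over the list alone. The list's median was -1.70 (camera adjusted p = 1.84e-05). With an estimated correlation the adjusted p was 0.482. The geometric mean of the list was 93.3, 107 and 245 CPM in ruxolitinib pools 1, 2 and 3, and 522, 512 and 386 CPM in control pools 4, 5 and 6. Without ruxolitinib pool 3, the library nearest to the controls, the mean log2 change of the identity genes went from -1.69 to -2.26, with Cd8a at -2.35, Cd8b1 at -2.35 and Thy1 at -2.56.

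Red cell genes rose. All 14 measured erythroid genes rose, with a median log2 fold change of 6.99 (camera adjusted p = 3.36e-19, and adjusted p = 0.203 with an estimated correlation). Hba-a1 rose from 1030.4 ± 312 CPM to 92167 ± 37366 CPM (6.48 ± 0.50, adjusted p = 2.26e-05) and Hbb-bs from 745 ± 109 CPM to 48824 ± 27106 CPM (6.03 ± 0.51). Haemoglobin genes have near-identical copies, so the split between copies is uncertain. Together they took 17.8 ± 4.61% of all counts in the ruxolitinib libraries and 0.209 ± 0.0434% in controls (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

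Genes of the other marrow lineages were also higher in the ruxolitinib libraries. All 16 monocyte and macrophage genes rose (median 3.18, camera adjusted p = 1.52e-12, and 0.280 with an estimated correlation), among them the haem oxygenase gene Hmox1 (188 ± 42.7 to 4025 ± 1117 CPM, log2 fold change 4.42 ± 0.35) and the lysozyme gene Lyz2 (279 ± 153 to 3009 ± 827 CPM, 3.43 ± 0.44). Of 15 B cell and plasma cell genes, 14 rose and Vpreb1 did not pass (median 5.05, the same with genes at 0 set to their bound). The immunoglobulin genes Ighm (2.10 ± 0.25) and Igkc (2.44 ± 0.30) were the most abundant, and this list was the only one whose camera call (adjusted p = 3.13e-14) held with an estimated correlation (adjusted p = 0.0278). All 9 stromal and endothelial genes rose (median 4.15, camera adjusted p = 4.41e-07, and 0.203 with an estimated correlation), such as the niche chemokine gene Cxcl12 (3.84 ± 0.27) and the matrix gene Sparc (4.49 ± 0.36). Of 15 granulocyte genes 11 rose, 12 over the list alone, and Prtn3 fell (median 2.35, camera adjusted p = 0.00451, and 0.601 with an estimated correlation). Ngp, a neutrophil granule gene, rose from 737 ± 533 CPM to 3889 ± 1693 CPM (2.40 ± 0.54, and 3.15 without control pool 4). S100a8, an abundant neutrophil gene, had a value of 1.23 ± 0.52 that did not pass (adjusted p = 0.0674), and passed without ruxolitinib pool 3 (adjusted p = 0.0403) or control pool 6 (adjusted p = 0.0399). It also passed with DESeq2 (adjusted p = 0.0162), limma-voom (0.0474) and limma-voom with quality weights (0.00247).

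In the other lists of marrow cell markers some members rose and others did not pass or fell. Of 16 dendritic cell genes 10 rose, among them the MHC class II chaperone gene Cd74 (1.43 ± 0.23) and Cst3 (0.76 ± 0.23), while Batf3 and Xcr1, genes of conventional type 1 dendritic cells, fell (list median 1.19, camera adjusted p = 0.00239, and 0.203 with an estimated correlation). Cst3 no longer passed without ruxolitinib pool 2 (adjusted p = 0.0715), control pool 4 (0.0555) or control pool 5 (0.0741). Of 10 progenitor genes 6 rose, led in abundance by Lmo2 (4.28 ± 0.36), and none fell (camera adjusted p = 0.0286, and 0.30 with an estimated correlation). The progenitor gene Myb had a value of -0.16 ± 0.28 (adjusted p = 0.650). Of 7 platelet genes, Ppbp, Gp9, Vwf and Tubb1 rose, and the values of Pf4 (-0.63 ± 0.46, and 0.17 without control pool 6) and Itga2b (0.73 ± 0.31) did not pass (camera adjusted p = 0.219). Itga2b passed without control pool 6 (adjusted p = 0.00919) and with limma-voom quality weights (adjusted p = 0.00129). Of 6 CD4 and regulatory T cell genes, Cd4 (6.38 ± 1.79 to 100.4 ± 14.9 CPM, 3.98 ± 0.27), Zbtb7b (1.34 ± 0.30) and Cxcr5 rose and Gata3 fell (camera adjusted p = 0.138). Cd4 is also carried by mouse dendritic cells. Of 4 measured natural killer cell genes, the adaptor genes Tyrobp (2.58 ± 0.26) and Fcer1g (2.11 ± 0.24), which myeloid cells also use, rose, and the receptor genes Klra7 and Klre1 fell. With 4 members that list was not tested as a set. Genes that complete a count of 5 or fewer here and below were chosen after their values were seen.

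**Figure D1:**
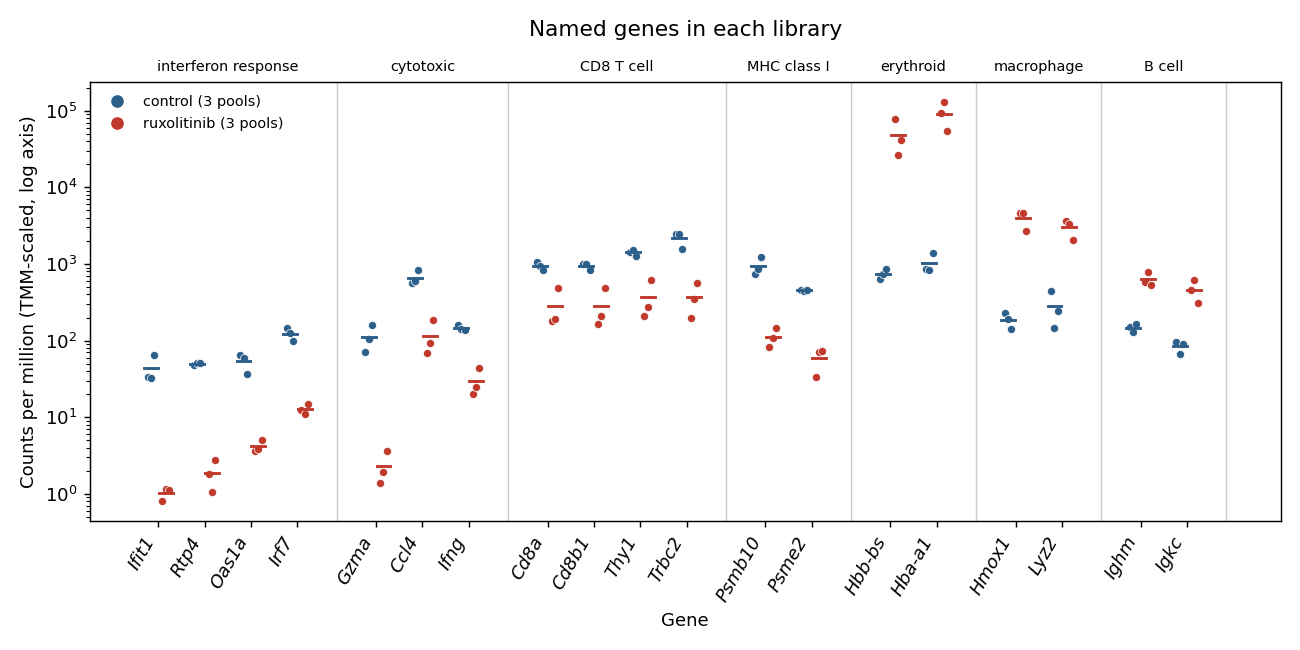
CPM values (vertical log axis, TMM-scaled) of named genes (horizontal axis) in each of the 3 control pools (blue points) and 3 ruxolitinib pools (red points), with short lines at the group means. Ifit1 averaged 43.7 CPM in controls and 1.03 CPM with ruxolitinib, Cd8a 944 and 286 CPM, and Hba-a1 1030.4 and 92167 CPM. When libraries are scaled to the CD8 identity genes instead, Ifit1 differs by -3.67 on the log2 scale. Cd8a differs by -0.08, but it is among the genes that set this scale, so its small value is not a separate result.

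Interferon-stimulated genes were mostly lower with ruxolitinib. Of 41 measured, 31 fell (32 over the list alone), 4 rose and 6 did not pass, with a median log2 fold change of -1.5, and the median was 0.22 when libraries were scaled to the CD8 identity genes. Besides Ifit1, the interferon regulator gene Irf7 fell from 123 ± 24.4 CPM to 12.7 ± 1.98 CPM (-3.28 ± 0.24, adjusted p = 1.95e-05) and the RNA-sensing enzyme gene Oas1a from 53.5 ± 14.9 CPM to 4.17 ± 0.769 CPM (-3.67 ± 0.29, adjusted p = 2.30e-05). Against these, the antiviral gene Rsad2 rose from 9.03 ± 1.40 CPM to 117 ± 40.3 CPM (3.69 ± 0.31), and Isg20, Irf8 and Irgm2 rose too. Neutrophils and macrophages also express Rsad2, and B cells and dendritic cells also express Irf8. The camera test gave adjusted p = 1.13e-09. With an estimated correlation the adjusted p was 0.288. Relative to the CD8 identity genes, which fell by a median of 1.70 in the same libraries, 8 of the 41 genes were lower and 9 higher at adjusted p under 0.05. Ifit1 (-3.67 ± 0.68), Oas1a (-1.82 ± 0.60) and Irf7 (-1.42 ± 0.56) were among the 8. Without ruxolitinib pool 2 the 8 became 3. This scaling put the median of all tested genes at 1.93, with 9346 genes higher and 83 lower, which applies to each list below.

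All 13 genes of MHC class I presentation fell, with a median of -1.54, which became 0.19 with libraries scaled to the CD8 identity genes and -0.18 with length and GC offsets added to that scaling (camera adjusted p = 7.54e-07, and adjusted p = 0.288 with an estimated correlation). The subunit genes of the immunoproteasome and its activator, which cut antigens into peptides, led the list. Psmb10 fell from 949 ± 259 CPM to 113 ± 32.0 CPM (-3.07 ± 0.32), Psme2 from 453 ± 11.4 CPM to 58.9 ± 22.1 CPM (-2.94 ± 0.32), Psmb8 by 2.51 ± 0.31 and Psme1 by 2.34 ± 0.26 on the log2 scale. Relative to the CD8 identity genes, Psmb10 (-1.33 ± 0.56, adjusted p = 0.0271) and Psmb9 were lower, while Psme2 was not past the threshold (-1.16 ± 0.56, adjusted p = 0.0534). Of this list, 2 genes were lower (0 adjusted over the list alone) and 0 higher under that scaling, 0 were lower without ruxolitinib pool 1 or any 1 control pool, 1 was lower without ruxolitinib pool 2, and 3 were lower and 4 higher without ruxolitinib pool 3.

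Cytotoxic effector genes fell as well. Of 26 measured, 16 fell, Lamp1, Zeb2 and S1pr5 rose and 7 did not pass, with a median of -1.83, close to the -1.70 of the CD8 identity list (camera adjusted p = 0.000106, and adjusted p = 0.30 with an estimated correlation). Ifng, which encodes interferon gamma, fell from 145 ± 11.6 CPM to 29.7 ± 12.6 CPM (-2.29 ± 0.30, adjusted p = 0.000242), and the chemokine genes Ccl4 and Ccl3 fell by 2.53 ± 0.37 and 1.97 ± 0.32 on the log2 scale. Lamp1, a lysosome membrane gene (1.97 ± 0.24), and Zeb2, a transcription factor gene of effector T cells and myeloid cells (2.60 ± 0.29), rose together with the macrophage list. Relative to the CD8 identity genes the cytotoxic median was -0.12, which turned to 0.31 when length and GC offsets were added (7 higher, 2 lower). Gzma (-4.0 ± 0.64, adjusted p = 3.45e-09) and Gzmb were lower, 6 genes were higher, and Ifng did not pass (-0.57 ± 0.55, adjusted p = 0.343). Without ruxolitinib pool 3, 6 were lower and 9 higher. Without ruxolitinib pool 1 or control pool 4, 1 was lower and 4 were higher, and without control pool 5, 2 were lower and 3 higher.

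Part of the inhibitory receptor and activation genes fell. Of 17 inhibitory receptor and exhaustion genes 8 fell and none rose, with a median of -0.83 that turned to 0.96 under CD8 identity scaling (camera adjusted p = 0.0149, and 0.601 with an estimated correlation). Cd160 (-3.28 ± 0.36), Cd244a (-1.86 ± 0.33), Lag3 (-1.75 ± 0.40, and -2.40 without ruxolitinib pool 3) and the transcription factor gene Batf (-1.73 ± 0.37) led the falls, and under that scaling Cd160 alone of the list was lower (-1.63 ± 0.57, adjusted p = 0.00725) and 7 genes were higher, 4 without control pool 4 and 3 without control pool 5. Of 18 activation and co-stimulation genes 10 fell and none rose, with a median of -0.79 that turned to 0.91 under CD8 identity scaling, with 6 higher and none lower (camera adjusted p = 0.0300, and 0.601 with an estimated correlation). The co-stimulatory receptor genes Tnfrsf9 (-2.01 ± 0.39) and Tnfrsf18 (-1.58 ± 0.38) and the surface genes Cd5 (-1.21 ± 0.31) and Slamf1 (-1.55 ± 0.47, and -2.46 without ruxolitinib pool 3) had the smallest p. Without ruxolitinib pool 2 the activation list's adjusted p was 0.0629. Slamf1 no longer passed without ruxolitinib pool 1 (adjusted p = 0.101) or pool 2 (0.0629), and Cd5 without pool 1 (0.0535). Under CD8 identity scaling the medians of both lists lay below the 1.93 of all genes.

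Of 20 measured naive and memory T cell genes, 10 rose (11 over the list alone), Ly6c2 and Lef1 fell and 8 did not pass, with a median of 0.73, which was 2.62 under CD8 identity scaling (camera adjusted p = 0.313). The largest called changes by p were in Il6ra, an interleukin 6 receptor gene that myeloid cells also express (3.23 ± 0.36), Igfbp4 (2.54 ± 0.29), Actn1 (1.88 ± 0.26) and Ly6c2 (-2.92 ± 0.30), which encodes a surface protein of memory T cells and monocytes. Of 18 chemokine receptor and adhesion genes, 5 rose, among them Cxcr4, Itgae, S1pr5 and the lymph node homing gene Ccr7 (2.39 ± 0.35), and 7 fell, including Itgb7 (-1.74 ± 0.29) and the selectin ligand gene Selplg (-1.47 ± 0.26). The median of that list was -0.30, its mean 0.02 and its camera adjusted p 0.402, and the median was 1.5 under CD8 identity scaling. Ccr7 is also expressed by B cells and dendritic cells, whose lists rose in the same libraries.

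Cytokine signalling genes were split. Of 19 cytokine-induced STAT target genes, Bcl6 (2.72 ± 0.30), Bcl2l1 (2.51 ± 0.32), Osm and Ccnd3 rose, the kinase gene Pim2 (-2.56 ± 0.31), the survival gene Bcl2 (-1.88 ± 0.24), Socs1, Cish and Myc fell, and 10 did not pass (median -0.15, which was 1.76 under CD8 identity scaling; camera adjusted p = 0.563). Bcl2l1 encodes BCL-XL, which red cell precursors also need. With CD8 identity scaling 13 of the 19 STAT target genes were higher and 0 lower, against a median of 1.93 over all genes. There Pim2 was at -0.80 ± 0.56 (adjusted p = 0.181) and Bcl2 at -0.04 ± 0.56 (adjusted p = 0.954). Among 23 JAK kinases, STATs and receptor subunits 7 rose and 8 fell, 9 over the list alone (median -0.08, which was 1.79 under CD8 identity scaling; camera adjusted p = 0.335). Jak2, a target of the drug that also serves the erythropoietin receptor, rose from 42.1 ± 2.41 CPM to 79.3 ± 5.13 CPM (0.91 ± 0.18, adjusted p = 0.00211). Jak1, the other target, was at 270.0 ± 21.5 CPM and 320.4 ± 45.5 CPM (0.25 ± 0.21, adjusted p = 0.345). Jak3 (-1.02 ± 0.40, adjusted p = 0.0545) and Tyk2 (0.77 ± 0.32, adjusted p = 0.0670) did not pass. Jak3 passed without ruxolitinib pool 3 (-1.51, adjusted p = 0.0117) or control pool 6 (-1.33, adjusted p = 0.0106), and Tyk2 without control pool 4 (1.13, adjusted p = 0.0140). Both also passed with DESeq2 (adjusted p = 0.0207 for Jak3 and 0.0399 for Tyk2), limma-voom (0.0499 and 0.0427) and quality weights (0.000187 and 0.0344). Jak3 passed among protein-coding genes alone (adjusted p = 0.0464) and Tyk2 without a filter (adjusted p = 0.0263). Ifnar2, an interferon receptor gene, rose (1.83 ± 0.24), and Stat4 (-2.14 ± 0.34) and Il15ra (-1.35 ± 0.26) fell. Under CD8 identity scaling Ifnar2 was at 3.82, Stat4 at -0.48 (adjusted p = 0.428) and Il15ra at 0.48 (adjusted p = 0.483).

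Cell cycle genes did not move as a group under TMM scaling. Of 45 measured, 9 rose, 8 fell (5 over the list alone) and 28 did not pass (median -0.06, mean 0.14, camera adjusted p = 0.745 downward). Under CD8 identity scaling the median was 1.90, with 41 higher and none lower. That median is near the 1.93 over all genes under this scaling, so the size of the rise is not particular to this list. Of all 13480 tested genes 9346 were higher, a smaller share than in this list, and that difference was not tested. E2f2 (2.66 ± 0.32), E2f8 (2.20 ± 0.25) and the kinesin gene Kif20a (2.75 ± 0.51) rose, and the microtubule regulator gene Stmn1 fell (-2.14 ± 0.28). E2f2 is abundant in red cell precursors. Among 21 apoptosis and p53 target genes, Bcl2l1 rose and 9 fell, including the death receptor gene Fas (14.6 ± 0.038 to 4.32 ± 0.375 CPM, -1.75 ± 0.25, adjusted p = 0.000353) and Bax (-1.59 ± 0.22). The median of that list was -0.68, which turned to 1.15 under CD8 identity scaling (camera adjusted p = 0.0300, and 0.280 with an estimated correlation).

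Of 22 oxidative phosphorylation genes 16 fell and none rose, with a median of -1.03 that turned to 0.86 under CD8 identity scaling (camera adjusted p = 6.14e-05, and 0.30 with an estimated correlation). Cox7a2 (-1.71 ± 0.23), Ndufa1 (-1.62 ± 0.25), Ndufb5 (-1.60 ± 0.21) and Sdhb (-1.35 ± 0.20) had the smallest p. Gene length went with the fold change across all tested genes, with a median log2 fold change of -0.86 in the shortest eighth, which held 5 of these 22 genes, and 0.50 in the longest. Adding length and GC offsets to the CD8 identity scaling moved the median of the 22 from 0.86 to 1.06. The median of all genes under CD8 identity scaling was 1.93. Of 18 glycolysis genes 8 fell, among them Ldha (-1.88 ± 0.25), Hif1a (-1.5 ± 0.34) and Tpi1 (-1.09 ± 0.22), and the hexokinase genes Hk2 (1.15 ± 0.27) and Hk1 and the kinase gene Pdk1 rose. The glycolysis median was -0.75, which turned to 1.16 under CD8 identity scaling (camera adjusted p = 0.127), and without control pool 6 the camera adjusted p was 0.0134. Counts of mitochondrially encoded genes were 2.25 ± 0.273% of each ruxolitinib library and 0.818 ± 0.0580% of each control library, and ribosomal protein genes took 4.58 ± 1.20% and 16.4 ± 1.14% (exact two-sided permutation p = 0.1 for each). Of 94 ribosomal protein genes, 30 were in that shortest eighth, and the same offsets moved their median under CD8 identity scaling from 0.13 to 0.47.

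Stress and inflammatory lists were mixed. Of 17 NF-kB and TNF target genes, Cd83 (3.18 ± 0.25), the interleukin 1 beta gene Il1b (3.10 ± 0.50) and Birc3 rose, Ccl3, Ccl4 and Bcl2a1b fell and 11 did not pass (mean 0.15, median 0.13, which was 2.01 under CD8 identity scaling; camera adjusted p = 0.910 downward). Of 15 unfolded protein response genes, Sel1l rose, Pdia6 (-1.17 ± 0.22), Sdf2l1 (-1.04 ± 0.23), Hsp90b1 (-0.85 ± 0.21), Edem1 (-0.62 ± 0.18) and Xbp1 fell, 4 over the list alone (median -0.18, which was 1.78 under CD8 identity scaling; camera adjusted p = 0.279). Of 17 immediate early and heat shock genes 12 rose and Jund, Junb (-1.02 ± 0.30) and Hspa8 (-0.90 ± 0.25) fell, 4 over the list alone (median 0.95, which was 2.83 under CD8 identity scaling; camera adjusted p = 0.127). Junb did not pass without ruxolitinib pool 1 (adjusted p = 0.0842), ruxolitinib pool 2 (0.0646) or control pool 5 (0.0781). Hspa8 did not pass without ruxolitinib pool 2 (adjusted p = 0.0513) or control pools 4 (0.0606) or 5 (0.0567), nor did Edem1 without the same pools (0.0661, 0.0557 and 0.0796).

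**Figure D2:**
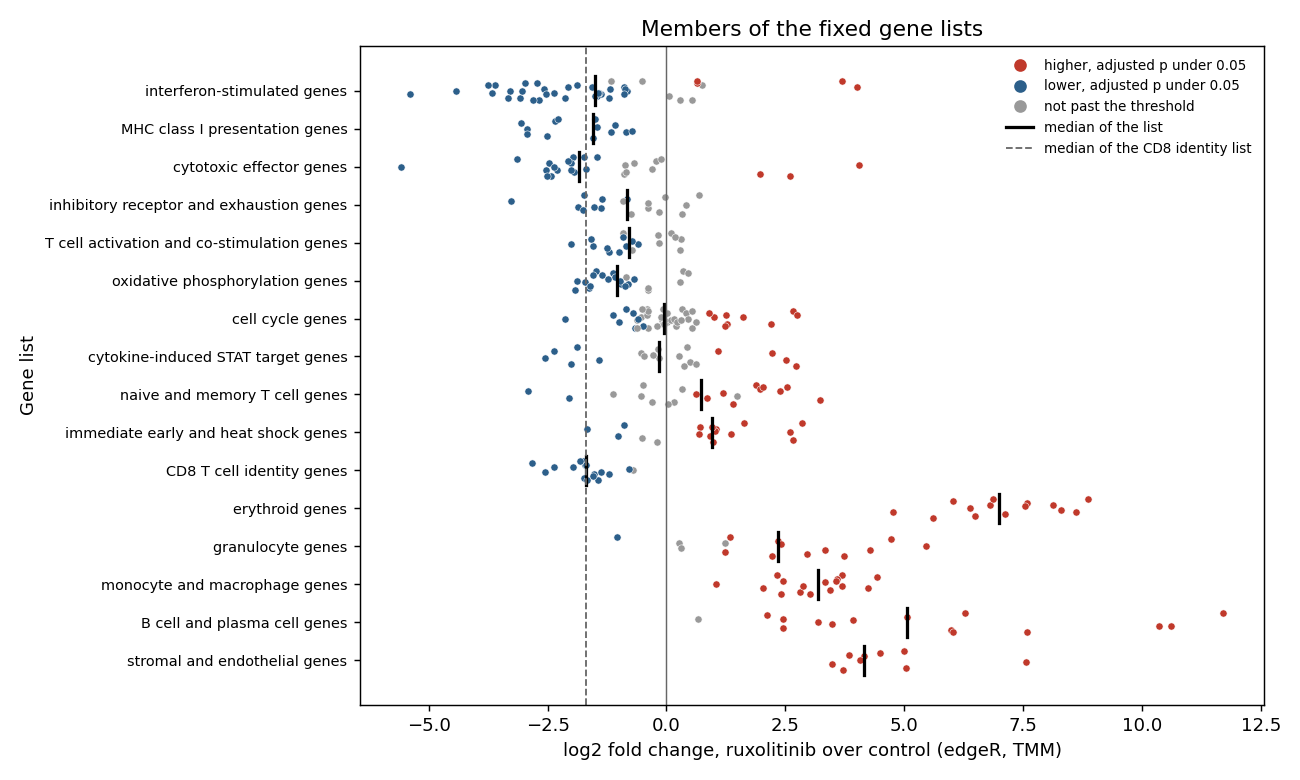
Log2 fold change of ruxolitinib over control (horizontal axis) for each measured member of 16 gene lists (vertical axis), coloured red where higher and blue where lower at adjusted p under 0.05 and grey otherwise, with a black line at each list's median and a dashed line at the CD8 identity median of -1.70. Erythroid genes centre on 6.99 and interferon-stimulated genes on -1.5, while the medians of the interferon, MHC class I, exhaustion, activation, oxidative phosphorylation, cell cycle and STAT target lists lie above 0 when libraries are scaled to the CD8 identity genes (0.22, 0.19, 0.96, 0.91, 0.86, 1.90 and 1.76). The median of all tested genes was 1.93 under that scaling.

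Across the genome, 7444 of 13480 tested genes (55.2%) changed with ruxolitinib, 4037 of them higher and 3407 lower, and 5746 by at least 2-fold. Scaling to the CD8 identity genes instead, an alternative chosen after seeing that this list fell, moved the median of all genes from 0.03 to 1.93 and gave 9346 genes higher and 83 lower, so that 99.1% of the calls were higher against 54.2% under TMM scaling. For each list described above with no member called higher or none called lower, edgeR at unadjusted p under 0.05, DESeq2 and limma-voom also called 0 members in that direction. Leaving out 1 pool gave between 5750 and 8313 genes, the lowest without ruxolitinib pool 1, and the camera test called 15 of the 26 lists, of which 1 held with an estimated correlation.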

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

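The scaling to the CD8 identity genes, the removal of haemoglobin genes, total-count scaling and the combined length and GC offsets were chosen after seeing the data; the other alternatives were fixed before. Under RLE or upper-quartile factors, no filter, a stricter filter, DESeq2 (8055 genes), limma-voom (7596), quality weights (9186), protein-coding genes alone, a 2-fold minimum (5746) and removal of haemoglobin genes (7506), the numbers of genes changed, higher and lower stayed within 1.5 times those reported. Leaving out each pool gave 5750 to 8313 genes, with 3444 to 4482 higher and 2306 to 3831 lower. Scaling to the CD8 identity genes gave 9346 higher and 83 lower in place of 4037 and 3407, as the scale moved the median of all genes; 4393 of its 9429 calls were among the 7444, 4120 of them in the same direction.

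With an estimated correlation 14 lists lost their camera call, among them the interferon list (adjusted p = 0.288) and the cytotoxic list (0.3002), and the cause was not tested. Leaving out each pool gave adjusted p of 2.38e-11 to 1.78e-08 for the interferon list, 0.4157 to 0.6419 for the STAT targets, 4.44e-08 to 0.000470 for the cytotoxic list and 0.2736 to 0.9402 for the cell cycle list, whose direction turned without ruxolitinib pool 3 (0.8158). The cell cycle list also turned with quality weights (0.7949) and fry (0.7194), and the NF-kB list with limma-voom (0.9986), fry (0.3901) and without ruxolitinib pool 2 (0.9414; range 0.5397 to 0.9902); neither passed the threshold in any of these, and the cause was not tested. With fry the exhaustion (0.06535) and activation (0.0631) lists no longer passed, while the naive and memory (0.02532), immediate early (0.0005139), CD4 (0.002048) and platelet (0.0426) lists did, and glycolysis passed with quality weights (0.0213). Under CD8 identity scaling with fry, 13 lists turned upward, 2 of them (cell cycle and NF-kB) with fry alone and 11 under a scale that moved the median of all genes from 0.03 to 1.93: interferon (0.5543), STAT targets (0.03885), cytotoxic (0.2153), cell cycle (0.0571), exhaustion (0.03825), activation (0.02306), JAK-STAT (0.03479), chemokine (0.02846), apoptosis (0.05623), glycolysis (0.05711), oxidative phosphorylation (0.1711), NF-kB (0.02581) and unfolded protein response (0.04609). In the same fry test the MHC class I list (0.6883) and the CD8 identity list (0.5205), which sets the scale, stayed downward but no longer passed.

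Of the named genes, Pf4 turned with quality weights (log2 0.19) and without control pool 6 (0.17; range -0.94 to 0.17), and Myb without control pool 6 (0.068; range -0.37 to 0.068), none past the threshold in the reported fit. Under CD8 identity scaling 22 named genes turned: Tnfrsf18 (0.13), Cd5 (0.58), Il15ra (0.48), Itgb7 (0.045), Selplg (0.30), Bax (0.32), Fas (0.15), Tpi1 (0.83), Hif1a (0.25), Ndufb5 (0.27), Cox7a2 (0.17), Sdhb (0.52), Ndufa1 (0.27), Pdia6 (0.68), Sdf2l1 (0.84), Hsp90b1 (1.02), Edem1 (1.29), Hspa8 (1.02), Junb (0.80), Jak3 (0.73), Myb (1.78) and Pf4 (1.21). A further 22 kept their direction but no longer passed, 4 passed that had not, and 54 kept both. Among the 22 were Pim2, Bcl2, Ifng, Stmn1, Ly6c2, Cd244a, Batf, Lag3, Tnfrsf9, Slamf1 and Stat4. So were Psme2, Psme1, Psmb8, Ldha, Ccl4 and Ccl3, and also Cd8a, Cd8b1, Thy1 and Trbc2, which help set the scale. With haemoglobin genes removed, all named genes left and all 26 lists kept direction and call. No paired analysis was possible because the pools of the 2 groups share no number. Counting depth limits genes near 1 CPM, and with 3 pools a group the simulation recovered few 2-fold changes.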

Other observations

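Genes of eosinophils and basophils, which no fixed list held, were higher in the ruxolitinib libraries. In a list written after the data were seen, all 12 measured genes rose (median log2 fold change 3.75, or 5.76 under CD8 identity scaling). The eosinophil granule protein gene Prg2 rose from 7.49 ± 10.8 to 185 ± 44.2 CPM (log2 fold change 4.61 ± 0.97), the eosinophil peroxidase gene Epx from 1.73 ± 2.34 to 42.4 ± 7.36 CPM (4.57 ± 0.76) and the chemokine receptor gene Ccr3 from 14.7 ± 4.74 to 153 ± 39.7 CPM (3.38 ± 0.31). The basophil protease gene Mcpt8 rose from 1.24 ± 1.31 to 9.76 ± 2.77 CPM (2.94 ± 0.67). Without control pool 4 the median was 5.36, Prg2 was at 7.13, Epx at 6.76 and Mcpt8 at 4.24, and 11 of 12 genes rose without ruxolitinib pool 1 or 2, 12 of 13 without ruxolitinib pool 3 and 11 of 13 without control pool 5. In a list of haem synthesis and iron handling genes written at the same time, all 16 rose (median 2.82, or 4.82 under CD8 identity scaling). The ferrochelatase gene Fech rose from 14.7 ± 1.39 to 1122 ± 411 CPM (6.25 ± 0.38), the mitochondrial iron importer gene Slc25a37 from 20.6 ± 2.10 to 1340 ± 545 CPM (6.02 ± 0.40) and the iron exporter gene Slc40a1, abundant in macrophages, from 71.8 ± 31.5 to 1104 ± 361 CPM (3.94 ± 0.41). The ferritin genes Fth1 and Ftl1, which most cells express, were already at 948 ± 214 and 1827 ± 457 CPM in controls. Adjusted over these 2 lists, limma's camera gave adjusted p = 1.67e-05 and adjusted p = 1.64e-12, and adjusted p = 0.138 for each with an estimated correlation. Both lists were written after the data were seen, so these p-values give no separate support for the rise. Selection with CD8 beads is meant to leave out eosinophils, basophils and red cell precursors, yet these transcripts were present in the selected libraries.

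T cell receptor beta V segments differed from pool to pool. The most used of the 22 segments in the table was Trbv17 in control pool 4 (22.6%, exact 95% interval 21.5 to 23.6% of 6336 Trbv counts), Trbv29 in control pool 5 (24.3%, 22.9 to 25.7% of 3497) and Trbv14 in control pool 6 (23.0%, 20.7 to 25.3% of 1345). In the ruxolitinib pools it was Trbv13-2 in pool 1 (15.9%, 13.7 to 18.3% of 1005), Trbv29 in pool 2 (15.5%, 13.6 to 17.6% of 1288) and Trbv26 in pool 3 (14.3%, 13.2 to 15.5% of 3713). The effective number of segments, the inverse of the summed squared shares, was 10.7 ± 0.596 (SD) with ruxolitinib and 9.75 ± 0.127 in controls (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give; 3 of 3 ruxolitinib pools above all controls). The measure was chosen after the counts were seen, and V segments share sequence, so single segments are uncertain.

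The tests of haemoglobin, of the cell mix, of T cell content, of length and GC and of natural killer cells in the paragraphs that follow were chosen after the results, or the gene values they rest on, had been seen. The splits of the libraries were planned, but the CD8 identity scaling used for some of them was not. The criterion for T cell content alone was also replaced after its results were seen. The first criterion counted interferon and MHC class I genes whose upper 95% bound lay under the lowest identity gene (3 of 54, with 5% as limit), and cytotoxic genes lower after CD8 identity scaling (2 of 26, with the same limit). Lower after that scaling were 8 of 41 interferon genes and 2 of 13 MHC class I genes (8 and 0 adjusted over each list alone). The criterion used below sets a limit from the spread of the identity genes and each gene's SE. The interferon genes exceeded the limit by each of these criteria, but the cytotoxic genes exceeded 5% with all 6 libraries only by the scaling count, so the reading of the cytotoxic list rests on the choice of criterion.

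The pattern weighed in this paragraph is the fall of T cell identity genes with the rise of marrow lineage genes. Haemoglobin counts that displace other genes do not account for all of it: under total-count scaling, removing those genes moved the median gene by 0.28 and the identity median from -1.60 to -1.35 (SD 0.55 over genes; 12 of 17 genes lower). A smaller T cell share over an unchanged mix of other marrow cells would raise all other lineages alike, but the erythroid median lay 4.643 above the granulocyte median (two-sided permutation p = 2e-05 over genes, which are not independent). More cells of other lineages in a changed mix stays open, since the data hold no count of cells apart from the transcripts that make up the pattern. Whether such cells came through the bead selection because treated marrow held more of them, an effect of the drug, or because the selection itself differed was not tested.

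Some interferon-stimulated and MHC class I genes lay below the CD8 identity genes, though with CD8 identity scaling the list medians did not (0.22 and 0.19), except that of MHC class I once length and GC offsets were added (-0.18, against 0.0012 for the identity genes). With fewer T cells alone, about 1.02 of the 41 interferon genes would lie below the limit that the spread of the identity genes and each gene's own SE allow, and 6 did (Ifit1, Oasl1, Usp18, Oas1a, Xaf1 and Irf7; exact one-sided binomial p = 0.000517; 5 to 8 genes when each pool was left out), which argues against T cell content as the whole cause, although these genes are regulated together and the p, which takes them as independent, is too small. For MHC class I it cannot be told apart from that cause: 1 of 13 genes, Psmb10, lay below (exact one-sided binomial p = 0.281, and 0 to 2 genes with each pool left out). The limit takes a gene's transcripts to come from T cells alone, which was not checked for either list. Length and GC bias as the whole cause would remove the calls under CD8 identity scaling, but with length and GC offsets 10 of the 41 interferon genes were lower, the 8 called before among them, while for MHC class I, with 1 of 13 genes (Psmb9), it cannot be excluded. Rsad2 and Isg20 rose against the pattern, and a lower interferon signal in the treated T cells, a response of the identity genes themselves to the drug, or a different mix of T cells or of other interferon-responding cells, may each underlie it; none of these was tested.

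Cytotoxic genes lay apart from one another under TMM scaling (SD of log2 fold changes over genes 1.91). They also did once libraries were scaled to the CD8 identity genes, with Gzma far below in both. By the replacement criterion the list as a set cannot be told apart from fewer T cells alone. Of 26 genes 1, Gzma, lay below the limit described for the interferon genes (exact one-sided binomial p = 0.482, and 1 to 2 genes with each pool left out). The limit for Gzma was -3.21 against an identity mean of -1.69, so the criterion would miss a moderate further fall across the list. Fewer natural killer cells in the treated marrow, a candidate source of low Gzma, cannot be told apart. Of the receptor genes in the natural killer list only 2, Klra7 and Klre1, were measured. After the scaling 1 of them was lower (both when adjusted over the list alone). Selection with CD8 beads is meant to leave out natural killer cells, but transcripts of other unselected lineages were present in these libraries. Under that scaling Gzma was at -4.0 ± 0.64.

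The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Each of the other splits mixes pools of both groups, so the difference between groups adds to their spread and lowers their gene counts. Those counts therefore do not tell how many genes would be called without a drug effect. The real split, 1 of the 10, gave 7444 genes and the highest other split 0 with edgeR (at unadjusted p under 0.05 at most 430.0 genes, and 0 with limma-voom). With CD8 identity scaling it gave 9429 genes, again alone (1 split), and the highest other 0 (at unadjusted p under 0.05 at most 2233 genes, and 0 with limma-voom). For the camera p under these permutations of the libraries, 2 splits, the real one included, were as small for the interferon genes (real p = 1.74e-10, smallest other 7.52e-12), 3 for the STAT targets (0.52, smallest other 0.354), 4 for the cytotoxic genes (3.66e-05, smallest other 1.65e-07) and 9 for the cell cycle genes (0.717, smallest other 8.49e-07).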
